A study of Homo sapiens with 8 samples.

How the data were processed

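The series profiled RNA sites crosslinked to RBM45, an RNA-binding protein, by iCLIP, which sequences RNA fragments recovered with a protein after ultraviolet crosslinking. The cells were SH-SY5Y, a human neuroblastoma cell line, carrying a FLAG-HA-tagged RBM45, per the labels. They were kept for 7 days in neuronal differentiation medium with 0.1% DMSO alone or with 10 µM RA (retinoic acid) in 0.1% DMSO. The labels describe 8 libraries in 4 groups of 2: CLIP and size-matched input RNA for DMSO and for RA. Nothing in the labels says that the replicates came from separate cultures.

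The values analysed were 2 deposited peak lists, 1 per condition, each combining the replicates of its condition. Per the submitters' processing notes, the tools used in the series included HISAT2, MACS2 2.1.1.20160309, bedtools 2.25.0, HOMER 4.11.1 and deepTools 3.2.1, and the builds hg19 and mm10, with no role given for any of them. Contig names in both lists were those of hg19, and all coordinates are given on that build, counted from 1. Per the peak names deposited in the lists, every entry was a MACS2 call from replicate 1, and the lists were named as overlaps. The entries were therefore read as replicate 1 calls that overlapped replicate 2, by a rule not given in the sources used here. Position and summit were deposited in base pairs.

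The score deposited for each peak equalled the whole part of 10 times its −log10 p in all 14294 entries. The fold enrichment over local background is the authors' ratio for each peak, and was used to describe peaks within a list and to recover reads, while peaks were ranked, and the stronger part of each list taken, by score. The −log10 p and −log10 q were also deposited by the authors, with the weakest p just under 0.001. Which library served as the control of the caller is not given in the sources used here.

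Reads were recovered from these values. MACS2 writes the fold as scaled reads plus a pseudocount of 1 over background plus 1, and p as a Poisson tail. The fold steps of peaks at the genome-wide background gave the worth of 1 CLIP read, 0.769 in the DMSO list and 0.320 in the RA list. Together with p they then gave the whole number of CLIP reads at each summit and the local background in control reads. A solution within 0.002 of the deposited −log10 p was found for 100% of DMSO peaks and 99.9% of RA peaks, and it was the only one for 99.6% and 97.5%. On simulated peaks the procedure returned the true read number for 99.99% of 42432 DMSO peaks and 99.86% of 6566 RA peaks. The simulated fold and p were written by the same formula that the procedure assumes. This checks the inversion, not whether that formula holds for the deposited lists. The scaling put the CLIP depth of RA replicate 1 at 1.26 times that of DMSO replicate 1, and the control depth of DMSO at 1.90 times that of RA. Library totals were not used here, so absolute depth is unknown. Read numbers refer to replicate 1, and whether duplicate reads were removed is not given in the sources used here, so intervals cover counting error only.

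An annotation or genome of hg19 was not used here. The reference table at hand was of another assembly, and no coordinates were converted, so peaks were not assigned to genes, introns, exons or motifs. The tests that need them were not run: occupancy of 17 fixed gene lists, region composition, motif density and distance to splice sites. Tests planned per gene were run on 100 kb windows, per strand by peak midpoint, which was the fallback fixed before the data were examined.

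Windows and peaks named in the text followed a rule fixed in advance: the 10 windows with the most entries in each list, the 10 with the smallest Fisher p for a larger share of the RA list and the 10 for a larger share of the DMSO list, each with at least 5 entries over both lists, and the 5 peaks of highest score in each list. Ties at the last place were settled by the order of window names. Other sites are marked as chosen after their values were seen or as outside this rule.

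Entries of different lists were called overlapping if they shared at least 1 bp on the same strand. Shares by read number count each peak once, regardless of strand. Overlap was tested one-sided against 1000 shuffles that moved each RA peak within its chromosome. Windows with an RA entry that also held a DMSO entry were counted and tested with the same shuffles. The share of each list that fell in a window was compared by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment at 0.05 over windows with at least 5 entries. Its log2 ratio had 0.5 added to each count. This test compares 2 lists, not replicated conditions. It takes entries as independent draws, so clustering of entries can make its p-values too small. On 12 simulated windows with an 8-fold larger RA share the test called 97.9%, against 32.1% at 4-fold and 0% at 1-fold, over 20 simulations. These windows were taken from those with many DMSO entries, and RA entries were drawn singly, without clustering. The rates therefore do not describe windows with few or no DMSO entries, or clustered entries. The overlap count was checked on 400 planted shared peaks, of which 400 were found. Medians were compared by two-sided permutation tests with 100000 resamples, and shares are given with 95% Wilson intervals. Alternatives covered the overlap rule, strand, peak strength, list length, random background, merging of peaks within 50 nt, the minimum number of peaks, and, added after seeing the data, read minimums, depth, q, background and local shifts. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.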

Results

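RBM45 crosslinking sites were mapped in SH-SY5Y neuroblastoma cells after 7 days in differentiation medium with DMSO or with 10 µM RA, to compare sites between cells kept with and without RA. Each condition had 2 CLIP libraries and 2 inputs, and its replicates were represented by a single list of peaks, so no value below has a spread between replicates. The DMSO list held 12406 entries, made of 12148 peaks, and the RA list held 1888 entries, made of 1846 peaks. The rest of the entries repeated an interval on the opposite strand. Recovered CLIP reads at the summit had a median of 4 in DMSO, with a range of 2 to 2265, and of 10 in RA, with a range of 4 to 3003.

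Most of the densest DMSO regions also carried RA peaks. The densest DMSO window, chr7:23400001-23500000 on the minus strand, held 34 DMSO entries and 6 RA entries. Windows with 30 DMSO entries each lay at chr12:2300001-2400000 on the plus strand, chr13:108200001-108300000 on the minus strand and chr9:140600001-140700000 on the plus strand, and held 9, 6 and 3 RA entries. The window chr2:236400001-236500000 on the plus strand held 28 DMSO entries and 1 RA entry. At least 20 DMSO entries were held by 13 windows, of which 12 held an RA entry, and chr21:33600001-33700000 on the plus strand, with 20 DMSO entries, held 0.

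The other windows named for their DMSO entries were chr7:158200001-158300000 and chr13:108400001-108500000 on the minus strand, with 23 and 20 entries, and chr1:210800001-210900000 and chr20:30500001-30600000 on the plus strand, with 20 each. At least 6 RA entries were held by 13 windows, all of which held DMSO entries, and 4 of them were among the 13 with at least 20 DMSO entries. The highest RA count, 9 entries, was reached by 5 windows: chr10:43600001-43700000, chr12:2300001-2400000, chr20:30500001-30600000 and chr5:134200001-134300000 on the plus strand and chr13:102900001-103000000 on the minus strand. The window chr11:65200001-65300000 on the plus strand held 7 entries in each list, and its neighbour at chr11:65100001-65200000 held 6 in RA and 4 in DMSO. The window chr9:140500001-140600000 on the plus strand held 7 RA entries and 18 DMSO entries, and chr13:102800001-102900000 on the minus strand held 6 and 15. Most windows held few peaks: 3274 of the 5983 DMSO windows and 1141 of the 1416 RA windows held a single entry. Windows with at least 5 entries numbered 442 in DMSO, together 27.1% of the list, and 22 in RA, together 7.42%. Shuffles of the DMSO list within chromosomes gave a mean of 3.35 such windows in 100 draws and a highest of 5.

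**Figure D1:**
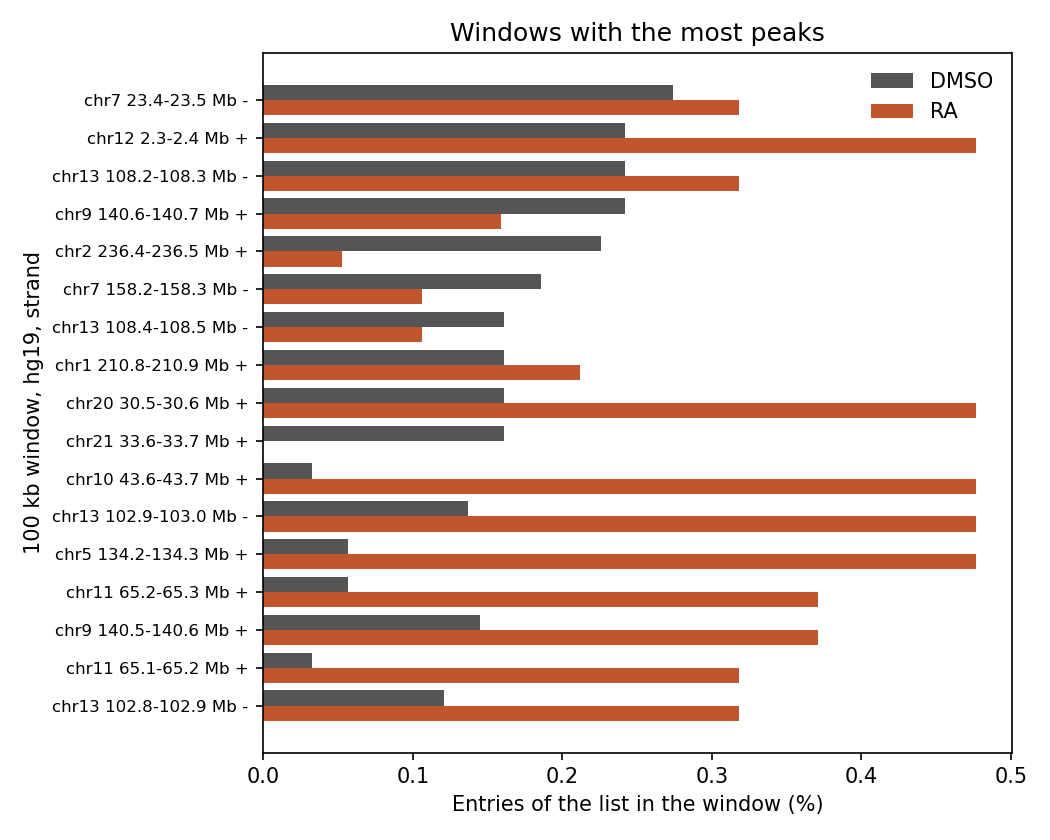
Share of each list, in percent of its entries, in the 17 windows of 100 kb (hg19, with strand) that were named for the most entries in either list; grey bars are DMSO and orange bars RA. The window at chr7:23400001-23500000 held 0.274% of the DMSO list and 0.318% of the RA list, while chr10:43600001-43700000 held 0.0322% and 0.477%.

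Some peaks lay in long stretches on a single strand. With gaps of at most 50 kb, 116 runs of at least 10 same-strand DMSO entries were found. Of these, 104 had no DMSO entry on the opposite strand and held 1920 entries, or 15.5% of the list, while 12 overlapped opposite-strand entries, in part the same intervals listed on both strands. The runs named here lie outside the naming rule fixed in advance. The longest run covered chr13:107888329-108516684 on the minus strand with 97 DMSO entries and 22 RA entries. Further runs held 71 DMSO and 17 RA entries at chr2:29569621-30118071 on the minus strand, and 68 DMSO and 28 RA entries at chr13:102585466-103051993 on the minus strand. The RA list had 3 such runs, with 2.65% of its entries, of which chr10:43589385-43635014 on the plus strand held 12 RA entries and 1 DMSO entry. The others, on the minus strand, held more DMSO entries: 28 RA and 61 DMSO at chr13:102637882-103043488, and 10 RA and 18 DMSO at chr2:29848365-29916260.

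The question of how far sites were shared between conditions was asked first at the level of single peaks. Of the 1888 RA entries, 470 overlapped a DMSO entry on the same strand (24.9%, 95% Wilson interval 23 to 26.9%). The same number of DMSO entries, 470 of 12406, overlapped an RA entry (3.79%, interval 3.47 to 4.14%). Shuffling RA peaks within chromosomes left a mean of 1.02 overlapping entries and at most 6 (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Shifting each RA peak by 1 to 50 kb, which keeps it near its site and was chosen after seeing the data, left a mean of 10.1 and at most 21 (same p). The share depends on the length of the DMSO list: cut at random to the length of the RA list, it left a median of 3.81% of RA entries with an overlap. Such a cut removes partners at random, so this fall follows from the cut itself.

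All 5 peaks of highest score in each list had a partner in the other. In DMSO the highest score belonged to chr12:2364763-2365458 on the plus strand, with 1011 reads and the authors' fold of 647. It was followed by chr2:149639338-149639414 on the plus strand with 1811 reads, chr5:134263624-134263701 on the plus strand with 703, chr5:73071717-73071786 on the plus strand with 206 and chr5:93905141-93905238 on the minus strand with 1328. In RA the order was chr2:149639358-149639417 on the plus strand with 3003 reads, chr5:134263617-134263707 on the plus strand with 1433, chr12:2364850-2365275 on the plus strand with 932, chr5:134263319-134263529 on the plus strand with 1433 and chr1:567143-567785 on the minus strand with 1524. Several of these sites also had a high background: 151 control reads at chr5:93905141-93905238 and 39.6 at chr2:149639338-149639414 in DMSO, against 0.204 at chr12:2364763-2365458.

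Overlap between the lists rose with the reads behind a peak. Among DMSO peaks, 0.566% of those with 2 to 3 reads overlapped an RA peak, 8.59% of those with 10 to 14 and 91.4% of those with at least 100 (32 of 35, interval 77.6 to 97.0%). Among RA peaks the share went from 9.57% at 4 to 5 reads to 64.8% at 100 or more (35 of 54, interval 51.5 to 76.2%). Peaks with a partner had a median of 14 reads in DMSO, against 4 for those without, and 16 against 8 in RA (two-sided permutation p = 1e-05 each, the smallest that 100000 resamples can give). They were also longer, with medians of 102 against 51 bp in DMSO and 65 against 51 bp in RA (same test and p). Longer peaks meet the 1 bp rule more easily, and reads and length were not separated here. At equal read numbers, not scaled for depth, the interval of the share at 100 or more reads in RA lay below that in DMSO. From 4 to 49 reads it lay above in each class, as at 25 to 49 reads with 57.3% in RA and 34.7% in DMSO. The shares also depend on the length of the list met, 12148 peaks for RA and 1846 for DMSO. Their order between the lists is therefore not a property of the sites alone.

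**Figure D2:**
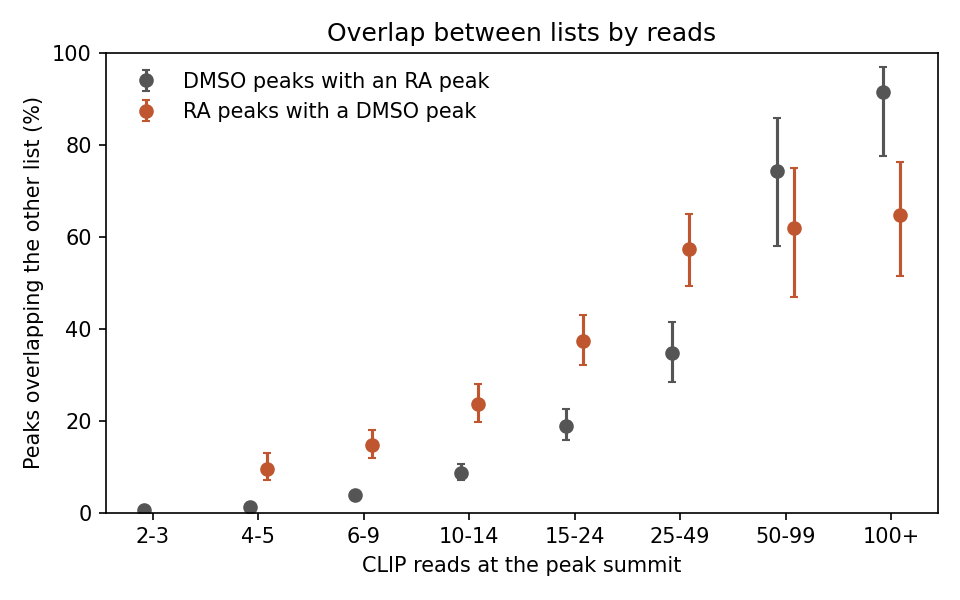
Percent of peaks that overlapped a peak of the other list (vertical axis) by the number of CLIP reads at the summit (horizontal axis), for DMSO (grey) and RA (orange); bars are 95% Wilson intervals. The DMSO share went from 0.566% at 2 to 3 reads to 91.4% at 100 or more, and the RA share from 9.57% at 4 to 5 reads to 64.8%.

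At the level of regions the lists had more in common. RA entries fell in 1416 windows and DMSO entries in 5983, and 1010 windows held both, which was 71.3% of the RA windows (interval 68.9 to 73.6%). Shuffled RA peaks shared a mean of 11% of their windows with DMSO, and at most 13.7% (one-sided permutation p = 0.001, the smallest possible). These shuffles take no account of genes or their expression, since the planned shuffle within genes was not run, so 11% is not the share that 2 lists drawn from the same expressed genes would have. With the DMSO list cut at random to the length of the RA list, the median share was 25.4%, a fall that again follows from the cut.

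The lists were then compared window by window for a different share of their entries. The test takes entries as independent draws, although entries clustered within windows, so its p-values can be too small. Of 566 windows tested, 5 passed the adjusted threshold, all with the larger share in RA. The largest counts lay at chr10:43600001-43700000 on the plus strand, with 9 RA and 4 DMSO entries (Fisher's exact test, adjusted p = 0.00295), and at chr5:134200001-134300000 on the plus strand, with 9 and 7 (adjusted p = 0.0081). In this chr5 window, the RA peaks with at least 100 reads lay close together, within chr5:134260198-134264051. Their background was 2 to 60 control reads, and that of such DMSO peaks 10 to 117. Windows at chr1:12600001-12700000 on the minus strand and chr5:82800001-82900000 on the plus strand each held 5 RA entries and 0 DMSO entries (Fisher's exact test, adjusted p = 0.00755 for each). The window chr11:30400001-30500000 on the minus strand held 5 RA entries and 1 DMSO entry (Fisher's exact test, adjusted p = 0.0242).

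The next RA-weighted windows did not pass. They were chr11:65100001-65200000 and chr11:65200001-65300000, chr3:159000001-159100000, chr2:178900001-179000000 and chr4:119800001-119900000, all on the plus strand, with adjusted p from 0.0648 to 0.206. With a minimum of 10 entries per window, the windows at chr11:65100001-65200000 and chr11:65200001-65300000 passed (Fisher's exact test, adjusted p = 0.0261 and 0.029), and in the stronger part of each list the first of them did (adjusted p = 0.0282). For a larger DMSO share 0 windows passed, and 0 had an unadjusted p under 0.05, against 42 for RA. The smallest p was that of chr21:33600001-33700000 on the plus strand, with 20 DMSO and 0 RA entries (Fisher's exact test, unadjusted p = 0.0982, adjusted p = 0.862). It was followed by chr13:113600001-113700000 on the plus strand with 18 and 0, and chr2:236400001-236500000 on the plus strand with 28 and 1. Next came chr13:94200001-94300000 on the plus strand with 13 and 0, level with chr7:136600001-136700000, which held the same 13 intervals on each strand, and then chr10:300001-400000 on the minus strand with 15 and 0. The last named by the rule held 10 DMSO and 0 RA entries: chr13:94500001-94600000 and chr17:55600001-55700000 on the plus strand and chr1:143100001-143200000 on the minus strand. They tied with others, 8 windows in all having the same p. Against 0 RA entries a window needed 26 DMSO entries for an unadjusted p under 0.05, while 2 RA entries against 0 were enough, so the short RA list left little power in the DMSO direction. With at least 4 reads required in both lists, 3 of the 5 windows passed, and those at chr5:134200001-134300000 and chr11:30400001-30500000 did not, with log2 ratios of the shares of 2.47 and 3.80 against 3.06 and 4.59.

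By chromosome, 0 of 24 differed in their share of the 2 lists after adjustment (Fisher's exact test, smallest adjusted p = 0.403), and 2 had an unadjusted p under 0.05.

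The DMSO list was 6.57 times as long as the RA list, and the ratio was largest among sites of few reads. In DMSO 5123 peaks (42.2%) rested on 2 or 3 reads, a level at which the RA list held 0 peaks, its weakest peaks resting on 4. These minimums follow from the caller's scaling. At 0.320 per CLIP read, 3 RA reads stay under 1 scaled read, too few for a call. At 0.769 per CLIP read, 2 DMSO reads were enough. The lack of RA peaks at 2 or 3 reads therefore does not show that weak sites were lost. With at least 10 reads there were 1785 DMSO peaks and 945 RA peaks, with at least 25 reads 272 and 246, and with at least 100 reads 35 and 54. Read depth at replicate 1 was 1.26 times higher in RA, so equal read numbers stand for different coverage. At equal coverage, a setting chosen after seeing the data, 2623 DMSO peaks with at least 8 reads stood against the 945 RA peaks, 436 with at least 20 reads against the 246, and 41 with at least 80 reads against the 54.

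**Figure D3:**
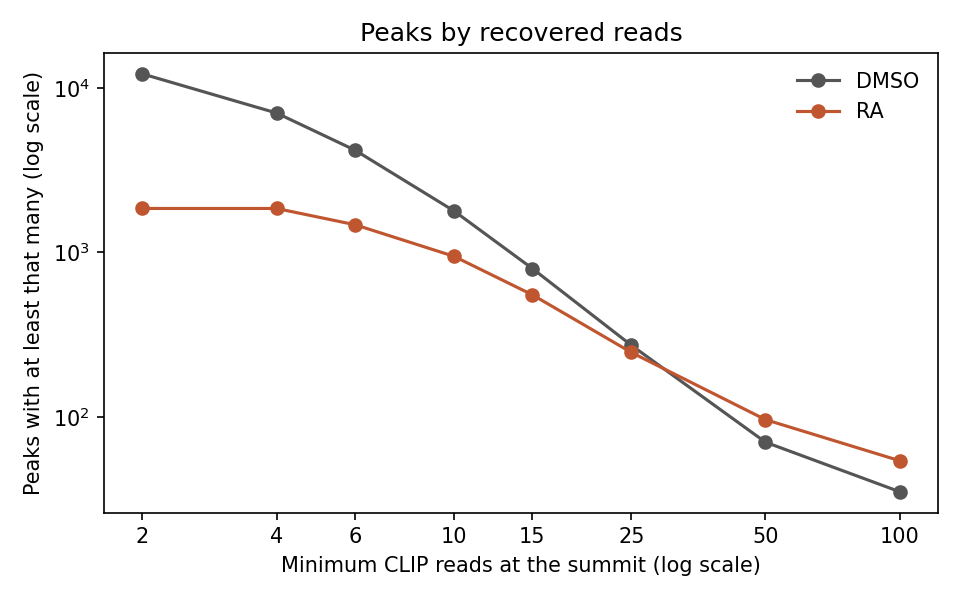
Number of peaks (vertical, log scale) with at least a given number of CLIP reads at the summit (horizontal, log scale) in the DMSO list (grey) and the RA list (orange), not scaled for depth. DMSO held 7025 peaks and RA 1846 with at least 4 reads, 272 and 246 with at least 25, and 35 and 54 with at least 100.

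Most peaks had the shortest length that the caller gave. This minimum of 51 bp was the length of 66.2% of DMSO and 67.8% of RA peaks, which sets the median of both lists, and the means of 72.4 and 72.7 bp did not differ detectably (two-sided permutation p = 0.816). In the stronger part of each list, from the median score up, the median was 60 bp in DMSO and 53 bp in RA (two-sided permutation p = 0.00895). The authors' fold had a median of 3.94 in DMSO and 3.84 in RA, and is not on a shared scale. Peaks with a q of 0.05 or more made up 28.9% of DMSO and 32.3% of RA peaks.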

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

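The tests below were chosen after the lists had been seen, except the one at low background, whose bound was written before its result.

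In DMSO 258 intervals and in RA 42 intervals were listed on both strands, and their entries are part of the comparisons above. On alternative or unplaced contigs lay 41 DMSO peaks (0.338%) and 18 RA peaks (0.975%), a share that was larger in RA (two-sided Fisher's exact test, p = 0.00064).

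The listing of an interval on both strands may come from a strand given after peak calling. Separate peak calls on each strand would differ in fold, p or summit, but the entries had the same values in all 300 such intervals, which argues against separate calls. A strand taken from overlapping genes stays open, since no annotation was used. If so, the single-strand runs of peaks reflect the genes and say nothing of strand by themselves. No biological explanation was tested.

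The RA list was shorter by a factor of 6.57. A higher read minimum in RA was tested by giving the DMSO peaks the read scale, depth and background of RA with Poisson noise. In 100 draws 7317 to 7523 still passed, on average 4.0 times the RA peaks. At replicate 1, this minimum alone thus left more peaks than the RA list holds. The draws cannot decide for the read minimum as a whole. That of replicate 2 is unknown, and the peaks used had already been selected as DMSO calls. Fewer CLIP reads in RA replicate 1 are argued against by a depth 1.26 times that of DMSO, and the overlap with replicate 2 as the whole cause by the numbers that listed replicate 1 calls reached, which were 2.11 times higher in DMSO (1.83 to 2.96 on the 23 chromosomes without Y). As a part of the cause the overlap cannot be told apart from an effect of RA: the listed share of numbered replicate 1 calls was 3.12 times larger in DMSO, but replicate 2 was not analysed here. Fewer RBM45 sites after RA, and a combination of these with the read minimum, stay open as well.

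Most RA peaks had no DMSO partner. Too few reads for a DMSO call would leave few strong RA peaks without one, yet of 246 RA peaks with at least 25 reads 147 had a partner (59.8%, 95% Wilson interval 53.5 to 65.7%), under the 90% set as bound. At a background under 1 read the share was 62.3% (114 of 183, interval 55.1 to 69.0%), but high background stays open: this bound was wrongly set on the background in the RA list, and the lists give no DMSO background for a site without a DMSO peak. Different sites called within the same regions stay open too: 68.4% of the 1418 entries without a partner lay in a window that held a DMSO entry, but this largely follows from the 71.3% of RA windows shared, and the shuffles take no account of genes. A change of sites with RA and loss of DMSO peaks in the overlap with replicate 2 both stay open.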

How the results depend on the processing

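The list length ratio, the reads at shared sites and alternatives by read minimum, q, background, depth, local shift, strand of windows and pairing of summits were chosen after seeing the data. Overlap of single peaks and of windows stayed above the shuffles in all alternatives run, with 3.81% to 30.7% of RA entries and 25.4% to 74.6% of RA windows shared. The lowest of both came from cutting the DMSO list, which leaves fewer peaks to meet. With 50% reciprocal overlap required, 13.3% of RA entries were shared. Windows past the threshold numbered 5, against 3 in the stronger part of each list, 3 with at least 4 reads and 4 with a minimum of 10 entries. In the stronger part and at 10 entries only 2 of the 5 windows were tested, and both passed. At 4 reads all 5 were tested and 3 passed. This minimum removed only DMSO entries, since RA peaks had at least 4 reads, so the changed ratios come from the DMSO entries removed. Of 109 values for named windows under alternatives, 104 kept their side of the threshold, a count that includes many windows far from it. It therefore says little about the 5 that passed. The 3 that passed newly were chr11:65100001-65200000 in the stronger part and at 10 entries and chr11:65200001-65300000 at 10 entries, and the 2 that no longer passed were chr5:134200001-134300000 and chr11:30400001-30500000 at 4 reads. The ratio of list lengths was 3.80 with at least 4 reads, 1.89 with at least 10 and 1.10 with at least 25, by removal of low-read peaks, and at equal coverage 2.78, 1.76 and 0.759 for at least 10, 25 and 100 RA reads. The median length of RA minus DMSO peaks was 0 bp overall and −7 bp in the stronger part, where the cause was not tested. Shared sites with more reads in RA and in DMSO numbered 41 and 49, and 13 and 32 without sites of high background, where fewer sites were tested (227 against 290).

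No paired analysis was possible because each condition had 1 combined list with no column per replicate. Alternatives for region composition, gene lists, motifs, splice distance and protein-coding background were not run, as they need an annotation or genome of hg19. The short RA list limits the window test: with 1888 RA entries, a window without RA peaks needed 26 DMSO entries to reach an unadjusted p under 0.05, and the highest count in any window was 34.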

Other observations

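The tests and sites in this part were chosen after their values were seen. At 290 sites where summits of overlapping peaks lay within 25 bp, recovered reads of the replicate 1 libraries were compared, scaled by depth. This compares 2 libraries, not the conditions, and covers counting error only. Only sites called in both lists enter, with at least 2 reads in DMSO and 4 in RA. The ratios therefore do not describe sites found in 1 list only, and their median is shaped by this selection. The median log2 ratio of RA over DMSO was −0.04, with quartiles of −0.79 and 0.66, and 41 sites passed with more reads in RA and 49 with more in DMSO (two-sided exact binomial test, adjusted over 290 sites). Without sites whose background was 1 read or more in either list, 13 of 227 passed with more reads in RA and 32 with more in DMSO. The control depth of DMSO was 1.90 times that of RA, so this cutoff is not the same background level in both lists. Reads of both lists correlated across sites (Spearman's rho 0.67), and sites are not independent replicates.

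Sites with more reads in RA and a background under 1 read included chr2:47388832-47388982 on the minus strand, with 39 reads in DMSO and 145 in RA (log2 1.56, exact binomial test, adjusted p = 1.27e-09). At chr9:100361699-100361779 on the plus strand there were 11 and 68 reads (log2 2.29, exact adjusted p = 1.43e-07). More reads in DMSO were found at chr7:23453755-23454973 on the minus strand, inside the densest DMSO window, with 158 and 67 reads (log2 −1.58, exact adjusted p = 1.36e-13). The same held at chr1:1789338-1789765 on the minus strand with 163 and 76 reads (log2 −1.44) and at chr3:65543500-65543555 on the minus strand with 39 and 7 (log2 −2.82). Starting at chr5:134263319, chr5:134263624 and chr5:134263877 on the plus strand, 3 neighbouring sites each passed with more reads in RA: 672 and 1433, 703 and 1433, and 992 and 1966. Their background was above 1 read in both lists, and 24 of the 41 sites with more reads in RA had such a background in at least 1 list, against 15 of the 49 with more in DMSO.

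Of the 54 RA peaks with at least 100 reads, 19 had no DMSO partner, and 13 of these lay over 10 kb from any DMSO peak. Background was under 1 read at 5 of the 19. Among those 5, chr4:1682059-1682124 on the minus strand had 226 reads, chr6:76735991-76736041 on the minus strand 132 and chr1:12665096-12665253 on the minus strand 110, the last inside a window that passed the test for a larger RA share. The strongest of the 19, chr2:88124420-88124518 on the minus strand, had 1057 reads over a background of 5.61. Of 35 DMSO peaks with at least 100 reads, 3 had no RA partner.

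At least 1 control read of background stood under 29 of the 35 DMSO peaks with at least 100 reads (82.9%), against 1.93% of all DMSO peaks, and under 44 of the 54 such RA peaks (81.5%), against 3.52% of all. These shares compare peaks within a list, since 1 control read stands for a different background level in each list. At chr9:137029535-137029585 on the minus strand the DMSO list had 2265 reads over a background of 1046 control reads.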
